A study of Mus musculus with 5 samples.

How the data were processed

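Total RNA of cells sorted from mouse cerebral cortex as parvalbumin-positive was measured in 5 samples, 3 WT and 2 KO for Clock, on single-colour Illumina bead arrays. Per the labels' protocols, RNA was extracted with Trizol and cleaned with an RNeasy kit and DNase I, amplified by whole-transcriptome amplification (NuGEN Ovation PicoSL V2) and biotin-labelled with an Encore BiotinIL kit. Groups and replicate numbers came from the sample titles, and ages and zeitgeber time from the labels.

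The deposited table of raw values gives, per the file headers, a signal and a detection p-value for each of 45281 probes on each array. The values are intensities on a linear scale, and the authors deposited them without normalization, as their differing array medians show (1121 on WT replicate 1 and 1687 to 1991 on the others). The deposited detection p-value sets each probe against background on the same array, and it falls as the intensity rises. A second table holds the authors' processed intensity values on a linear scale. Its 5 columns share a single distribution from -1132 to 18094, with medians between -2.00 and -0.10, and each ranks the probes as the raw intensities of the same array do, which is what background subtraction and quantile normalization give. The steps and their settings are not given in the sources used here. Per the submitters' processing notes, GenomeStudio was used, with no version given.

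Gene names came from the platform annotation supplied with the series, which can be old, with symbols updated through Entrez numbers to the RefSeq gene table of assembly GRCm38.p6, used for names only. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and were left unnamed, and 10378 had none. Updated symbols were found for 34807 probes.

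The raw intensities were background corrected and normalised with limma 3.58.1 in R 4.3.3 (neqc: normexp from the detection p-values, quantile normalization, offset 16, log2). Probes with a detection p under 0.05 on at least 2 of the 5 arrays were tested, 3347 probes (7.39%) of 2247 named genes, where 1023 probes would pass by chance if arrays were independent. Of all probes, 1038 were detected on all 5 arrays and 40117 on none. KO was compared with WT with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A probe not above background on any array of a group is given as a bound, its value raised to the lowest signal among detected probes of that array where it lay lower. Correlations between arrays are Pearson's across tested probes. No coordinates are given, as the tables name no genome build.

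Gene lists were tested with camera (preset correlation 0.01) on the brightest tested probe of each gene, with adjustment over the 13 lists that had at least 5 tested members, and member counts are given over all genes and adjusted over the list alone. Camera was repeated with an estimated correlation, and fry was run in its directional and mixed forms. The 26 lists, the tests, the filters, the alternatives and the rule for named genes were fixed before the data were examined. A list of proliferation markers was added afterwards. The rule named Clock and the measured members of the core clock and E-box lists, the 10 genes of smallest p in each direction where none passed, up to 3 members of smallest p in each other list, and Pvalb, Gad1 and Gad2; members of lists could be left out of the text, and those kept from lists that were not called are the members of smallest p, with Rps14 added as a ribosomal gene with a value of the other sign. Which members to keep was settled after their values were seen. Detection shares of lists were compared with Fisher's exact test, chosen after the detection values were seen.

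The test was also run on simulated data: 20 sets of 3347 probes with means and variances drawn from these arrays, 100 probes changed by 1 log2 unit and 100 by 2. For lists, values were drawn anew in each of the 20 sets, without the changed probes. The 15 genes of synaptic vesicle release, lowered by 0.5, were called in 100% of sets, and a mean of 0 of the 11 lists not shifted was called. That shift is larger than the mean of -0.23 found for this list, so the rate does not apply to it. The simulated probes vary independently, which real genes do not. All simulated arrays vary alike, while KO replicate 3 stood apart from the other arrays.

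Alternatives covered background correction, scaling, offset, the authors' processed values (set to at least 1 before log2), the filter on dim probes, the variance model, array weights, the replicate number as a block, age in days as a covariate, leaving out each sample, the threshold, a per-probe pooled-variance test, and the mean of a gene's probes. The arrays that remained were normalised anew. Where a group was left with 1 array, that array was assumed to vary like the other group. Cyclic loess was added after seeing the data.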

Results

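The series profiled total RNA of parvalbumin-positive cells sorted from mouse cerebral cortex, in mice that carry a green fluorescent reporter of parvalbumin expression. Parvalbumin is a calcium-binding protein of fast-spiking interneurons, which release the inhibitory transmitter GABA. A single-colour Illumina bead array of 45281 probes was read for 3 samples from mice with both copies of the circadian gene Clock (WT, replicates 1, 2 and 3) and for 2 samples from mice lacking it (KO, replicates 1 and 3). All 5 samples were taken at zeitgeber time 16 h, which counts from lights-on. The WT mice were 61, 64 and 64 days old and the KO mice 61 and 60 days. The labels do not say whether each sample is a separate animal, so p-values measure the spread between these samples, and the number of arrays limits their precision.

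Few probes stood above background. Probes with a detection p under 0.05 numbered 3671, 2744 and 2685 on WT replicates 1, 2 and 3, and 2709 and 1978 on KO replicates 1 and 3, against 2264 expected by chance on an array with no signal. These are 8.11%, 6.06%, 5.93%, 5.98% and 4.37% of all probes. KO replicate 3 thus lay below the chance count, and its correlation with the other arrays across the 3347 tested probes ranged from 0.751 to 0.827, while the other 4 arrays correlated with each other at 0.860 to 0.924. These correlations are across probes, which are not independent replicates. No 2 arrays were copies of each other.

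**Figure D1:**
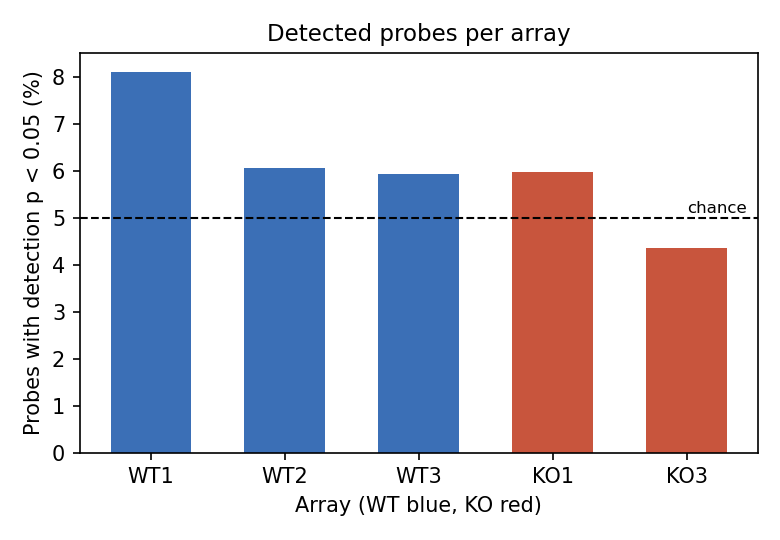
Percent of the 45281 probes with a detection p under 0.05 on each of the 3 WT arrays (blue) and 2 KO arrays (red), 1 bar per array. The dashed line marks the 5% that chance gives. WT replicate 1 reached 8.11% and KO replicate 3 stayed at 4.37%.

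The genes that were detected included markers of GABA-releasing neurons and genes of energy metabolism and protein handling. A gene counted as detected when a probe passed on at least 2 of the 5 arrays, which 2247 named genes did. Of the GABA neuron markers on the array, 7 of 14 were detected, among them Gad1 and Gad2, the enzymes that make GABA, and the vesicular GABA transporter Slc32a1. Detection also covered 10 of 21 fast-spiking ion channel genes, 15 of 32 genes of synaptic vesicle release, 50 of 79 genes of the mitochondrial respiratory chain, 10 of 22 glycolysis genes, 13 of 26 heat shock and unfolded protein genes, 11 of 33 antioxidant genes, 23 of 62 cytosolic ribosomal protein genes and 11 of 39 proteasome genes. Each of these shares exceeded that of other genes (about 11.8%) by Fisher's exact test, two-sided, adjusted over 26 lists, with the largest adjusted p at 0.0125 for the proteasome and the smallest at 6.2e-26 for the respiratory chain. This test was chosen after the detection values were seen, and genes are not independent. No other cell type was measured for comparison, so these shares do not set the sorted cells apart from others. Among parvalbumin interneuron markers 5 of 17 were detected (adjusted p 0.108 by the same exact test).

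Markers of the other cell types that a cortical sort can hold were detected at shares between 5.00% and 11.1%, none above that of other genes by the exact test. The counts were 2 of 19 for excitatory neurons, 2 of 20 for other interneurons, 2 of 18 for astrocytes, 1 of 17 for the oligodendrocyte lineage, 1 of 18 for microglia, 1 of 20 for endothelial and mural cells and 1 of 9 for blood cells. Perineuronal net and matrix genes reached 1 of 26, critical period plasticity genes 3 of 22, immediate early genes 4 of 29, GABA receptors 4 of 14, glutamate receptors 6 of 24 and histone genes 7 of 64. None of the 8 genes listed as repressed by REV-ERB was detected.

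The comparison of KO with WT asks what the loss of Clock changes in these cells, beginning with Clock itself and the circadian loop. Clock encodes the partner of BMAL1 in the transcription factor that drives the loop through E-box elements. None of the 3 Clock probes was above background on any of the 5 arrays, WT included, so they give no fold and do not check the genotype labels. Of 28 genes in the clock lists, 21 had no probe above background on any array, among them Arntl, Per1, Per2, Cry1, Nr1d1 and Dbp, and 6 had a tested probe. Core clock loop genes were detected at 3 of 19 and E-box targets at 5 of 19 (adjusted p 0.816 and 0.139 by Fisher's exact test).

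None of the 6 measured clock genes passed limma's test (smallest adjusted p over all probes 0.801). Cry2, a repressor of the loop, read 7.33 ± 0.062 (SD, n = 3) in WT and 7.74 ± 0.16 (SD, n = 2) in KO on the log2 scale, a difference of 0.41, with both KO arrays above all 3 WT arrays. Under median scaling, which moved the median of all tested probes by -0.39, the Cry2 difference was -0.35. With the remaining arrays normalised anew it was 0.13 without WT replicate 1 and 0.59 without KO replicate 1. In the main fit WT replicate 1 read 7.32, near the WT mean, so the drop to 0.13 does not come from its value alone. Nr1d2, which encodes the repressor REV-ERB beta, differed by -0.86, and most of this came from KO replicate 3 at 7.40, against 8.64 for KO replicate 1 and 8.84 to 8.95 in WT. Without KO replicate 3 the Nr1d2 difference was -0.25. The differences of Rora (-0.15), Tsc22d3 (-0.13), Tspan4 (0.12) and Tef (0.022) each changed sign under another setting or when 1 array was left out. The 5 tested E-box targets had a mean difference of -0.086 and a median of 0.022, and camera placed the list on the upper side (adjusted p 0.965), so mean and test differ in sign. No member passed over all genes or adjusted over the list alone, and the 3 detected core loop genes were too few for a list test.

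No single gene changed between genotypes past the threshold. With limma, 0 of 3347 tested probes had an adjusted p under 0.05, and the smallest adjusted p was 0.801. At an unadjusted p under 0.05 there were 198 probes, 101 higher and 97 lower in KO, where chance gives 167. A per-probe pooled-variance test also called 0 probes, with 157 at an unadjusted p under 0.05. The split between higher and lower depended on the scaling: it was 73 and 131 without background correction, 62 and 123 on the authors' processed values, 71 and 141 after cyclic loess (chosen after seeing the data), and 0 and 23 under median scaling. A comparison of 3 arrays with 2 has 10 splits, so an exact permutation test of a single gene cannot give a two-sided p below 0.1. In data simulated from these arrays for the 3347 probes, the same test called 63.9% of probes changed by 1 log2 unit and 97.6% of those changed by 2, with a mean of 8.9 false calls per simulation of 200 changed probes. The simulated arrays all varied alike, unlike KO replicate 3, and the 200 changed probes eased the adjustment. These rates therefore do not give the share of real changes that could be found here. When KO replicate 1 was left out, 27 probes passed, among them Nr1d2 (-1.61), Eno2 (-1.70) and H2ac13 (1.68), all against KO replicate 3 alone. Without any 1 of the other 4 arrays 0 did.

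The probes of smallest p with a higher value in KO are given as values, none of which passed. Ube4a, a ubiquitin chain assembly factor, read 7.10 ± 0.094 (SD, n = 3) in WT and 7.91 ± 0.0084 (SD, n = 2) in KO, a difference of 0.81 ± 0.15 (SE). Dbi, which encodes the acyl-CoA-binding protein and endogenous benzodiazepine receptor ligand, differed by 1.30, the histone demethylase Kdm5b by 0.81, the RNA-binding protein gene Tardbp by 0.56, the ubiquitin ligase gene Cblc by 0.65 and Coq3, of ubiquinone synthesis, by 0.56. The imprinted genes Ndn and Magel2 differed by 0.81 and 0.51, Olfr48 by 0.71 and Il18rap by 0.61. Median scaling moved the median of all tested probes by -0.39, and under it all 10 values were below 0, from -0.53 for Ndn to -0.11 for Kdm5b, with 8 of the 10 still above that median and Dbi (-0.44) and Ndn below it. Without WT replicate 1, the array with most detected probes, and with the remaining arrays normalised anew, the differences shrank by more than 1.5 times: Dbi to 0.84, Ndn to 0.36, Kdm5b to 0.21, Cblc to 0.20, Tardbp to 0.17, Coq3 to 0.21, Olfr48 to 0.21, Il18rap to 0.15 and Magel2 to 0.15. The new normalization changed the values as well, so this does not show that the differences rest on that array. In the main fit WT replicate 1 lay above the WT mean for Dbi (7.98 against 7.84), Ndn (7.88 against 7.62) and Coq3 (7.30 against 7.25). Leaving out its values alone would not shrink these differences. For Cblc it lay below (7.11 against 7.22). Ube4a was above background on no WT array but replicate 1, so it is given no value without that array. Kdm5b was detected on 2 of 3 WT arrays, Coq3 on 2 and Olfr48 on 1.

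Among the probes of smallest p with a lower value in KO was Pvalb itself. It read 8.95 ± 0.21 (SD, n = 3) in WT and 7.71 ± 0.73 (SD, n = 2) in KO, a difference of -1.24 ± 0.31 (SE), with 8.22 on KO replicate 1, 7.19 on KO replicate 3 and 8.79 to 9.18 in WT. Its 1 probe was detected on all 3 WT arrays and on 1 KO array. Adjusted over the list of parvalbumin interneuron markers alone Pvalb passed (limma adjusted p 0.0206), and over all probes it did not (0.801). In that list alone the smallest limma adjusted p was above the threshold without WT replicate 1 (0.0533), WT replicate 2 (0.113), WT replicate 3 (0.0575) or KO replicate 3 (0.110). With the remaining arrays normalised anew, without KO replicate 3 the Pvalb difference was -0.75 and without WT replicate 1, 2 or 3 -0.70, -1.20 or -1.45, while without KO replicate 1 the only KO array left was 1 on which Pvalb was not above background, so it is given there as at least 3.58-fold lower, and limma's adjusted p of 0.0423 rests on that background value. The remaining probes of this group were those of Sgtb, a co-chaperone of synapses (-0.66), Nnt, the mitochondrial transhydrogenase (-0.87), the diacylglycerol kinase gene Dgkq (-0.67), Tmx4 (-0.89), the respiratory complex I subunit gene Ndufa10 (-0.96) and Tmem263 (-0.66). These too shrank without WT replicate 1 and with the remaining arrays normalised anew, to -0.22, -0.38, -0.24, -0.27, -0.37 and -0.26 in the same order. In the main fit WT replicate 1 lay below the WT mean for Dgkq (7.88 against 7.98) and Pvalb (8.88 against 8.95). Leaving out its values alone would not shrink these differences. For Ndufa10 it lay above (8.33 against 8.30). Dgkq, Ndufa10 and Tmem263 were detected on 1 KO array. Rtn3 and Prf1 were not above background on either KO array and were at least 1.37-fold lower and at least 1.66-fold lower there, the bounds set by the lowest detected signals. For Ywhab, a 14-3-3 protein gene, 1 of 2 tested probes was likewise below background in KO (at least 1.56-fold lower), while the other differed by -0.49 and read 8.61 on KO replicate 1, inside the WT range of 8.18 to 8.69. Without WT replicate 1 the bounds were at least 1.12-fold for Rtn3, 1.14-fold for Prf1 and 1.16-fold for Ywhab.

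**Figure D2:**
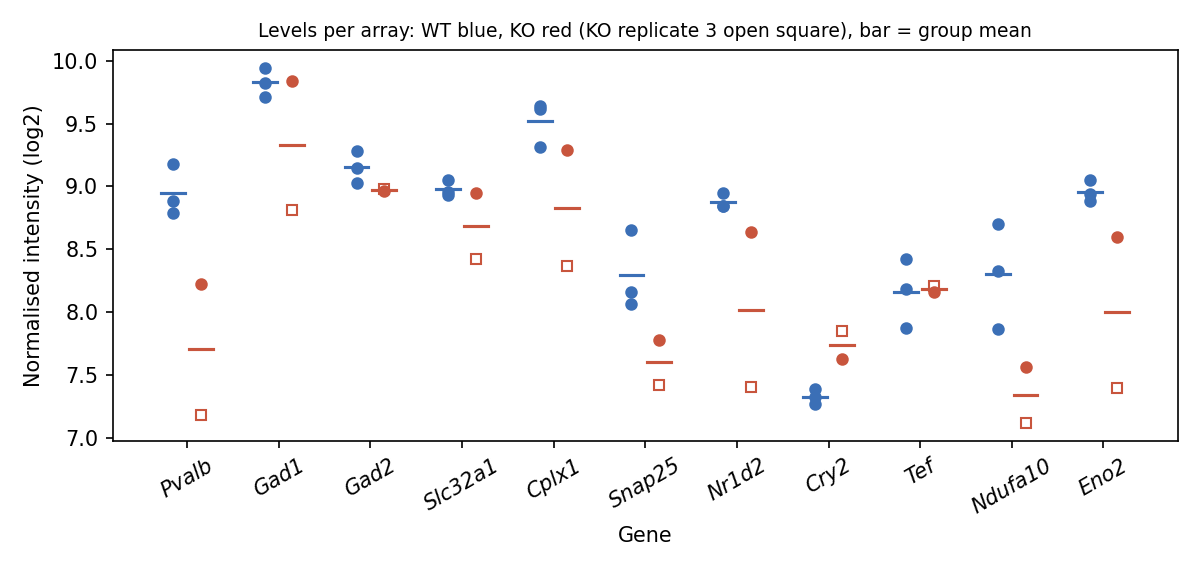
Normalised log2 intensity of 11 genes on each array, with WT in blue, KO in red and KO replicate 3 as an open square; bars are group means (n = 3 and n = 2). No gene shown passed the test over all probes: Pvalb differed by -1.24, Nr1d2 by -0.86 and Cry2 by 0.41 (Cry2 by -0.35 under median scaling), and Tef changed sign under median scaling, cyclic loess and without WT replicate 1 or KO replicate 3.

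As groups, 4 of the 13 gene lists with at least 5 tested members fell in KO relative to other genes by camera with a preset correlation of 0.01. Parvalbumin interneuron markers had a mean log2 difference of -0.42 over 5 genes (adjusted p 0.0343), GABA neuron markers -0.39 over 7 (0.00447), genes of synaptic vesicle release -0.23 over 15 (0.0167) and genes of the mitochondrial respiratory chain -0.24 over 50 (8.8e-06). The correlation between members was estimated at 0.19, 0.53, 0.16 and 0.44 in the same order, above the preset 0.01. With these estimates all 4 had a camera adjusted p of 0.753, and fry's directional test gave 0.635, so none was called by either. The calls therefore rest on the preset correlation. In the same order the means were -1.26, -1.16, -0.99 and -0.80 under median scaling, beside its median shift of -0.39, and -0.17, -0.17, -0.10 and -0.11 without background correction, and all 4 passed camera under both. Parvalbumin interneuron markers missed on the authors' processed values (camera adjusted p 0.0775) and with trend and robust eBayes (0.0721), 1 list was called with no filter on dim probes or with detection p under 0.01, and 0 of 6 with detection on all 5 arrays. Over all alternatives and samples left out, parvalbumin interneuron markers passed in 7 of 18, GABA neuron markers in 12 of 19, vesicle release in 10 of 20 and the respiratory chain in 15 of 20. These reruns reuse the same 5 arrays and are not independent. All of them but the estimated correlation and fry kept the preset correlation of 0.01. Members were lower in KO in 4 of 5, 7 of 7, 12 of 15 and 44 of 50 cases. No member of any list passed over all genes, and adjusted over the list alone the only one was Pvalb.

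The 5 tested parvalbumin interneuron markers were Pvalb (-1.24), the complexin gene Cplx1 (-0.70), the respiratory subunit gene Cox6a2 (-0.37), the potassium channel gene Kcnc2 (-0.13) and Vamp1 (0.32), a vesicle fusion gene. Kcnc2, Vamp1 and Slc32a1 were named after their values were seen. Among GABA neuron markers Gad1 differed by -0.50 and -0.56 on its 2 probes, Gad2 by -0.18, Slc32a1 by -0.29 and Nxph1 by -0.61, and Satb1, below background on both KO arrays, was at least 1.22-fold lower. The vesicle release genes included Snap25 (-0.69), Syn1 (-0.51) and Cplx1, and the respiratory chain genes Ndufa10 (-0.96), Cox6b1 (-0.60, with its second probe near 0) and Cox6a1 (-0.44). Cplx1 and Vamp1 belong to both the parvalbumin and the vesicle release lists, and Cox6a2 to both the parvalbumin and the respiratory chain lists. In each fit without an array the remaining arrays were normalised anew, which also changed the values. Without WT replicate 1 the differences were -0.16 for Snap25, -0.20 for Syn1, -0.20 for Nxph1, -0.19 for Cox6a1, -0.19 for Cox6a2, -0.37 for Ndufa10 and 0.090 for Vamp1, and Satb1 was at least 1.03-fold lower. Without WT replicate 2 Gad2 was at -0.11. Without KO replicate 3 the differences were -0.24 for Cplx1, -0.30 for Cox6b1, -0.032 for Slc32a1, -0.19 for Syn1, -0.25 for Nxph1, -0.13 for Cox6a2 and 0.014 and 0.28 for the Gad1 probes. Kcnc2 (0.11) and Vamp1 (-0.067) also changed sign there. Of the genes named here, Cox6a2, Nxph1, Syn1, Ndufa10 and Cox6a1 were, like Pvalb, above background on KO replicate 1 but not on KO replicate 3.

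The mean of each of the 4 lists lay further below WT on KO replicate 3, the array with the fewest detected probes, than on KO replicate 1. On KO replicate 3 the list means deviated from WT by -0.64 for parvalbumin interneuron markers, -0.66 for GABA neuron markers, -0.38 for vesicle release and -0.44 for the respiratory chain, against -0.21, -0.13, -0.079 and -0.052 on KO replicate 1. Many members were at background on KO replicate 3. Respiratory chain genes detected numbered 16 of 79 there, and 56, 49 and 33 on WT replicates 1, 2 and 3 and 40 on KO replicate 1. In the order above the other lists had 3, 4 and 8 detected there, and 5 to 9, 5 to 7 and 11 to 17 on the other arrays. Detection on any 2 arrays passed the filter, so members could enter through WT arrays where they were high. Single WT arrays deviated from the other WT arrays by -0.079 to 0.15, -0.33 to 0.17, -0.15 to 0.13 and -0.29 to 0.23, so KO replicate 1 lay inside the WT range for 3 of the 4 lists. KO replicate 3 was the lowest array for 10 of the 13 tested lists, and so not for these 4 alone. Of the 2 Gad1 probes, 1 read 9.84 on KO replicate 1, within the WT values of 9.71 to 9.94, and the other 10.09, above those of 9.63 to 9.95. Without KO replicate 3 camera called 0 lists, with means of -0.22, -0.096, -0.083 and -0.056 in the order above and adjusted p of 0.435 for parvalbumin interneuron markers and the respiratory chain and 0.667 for GABA neuron markers and vesicle release. Without WT replicate 1 it also called 0, with means of -0.31, -0.21, -0.16 and -0.077 (adjusted p 0.0756 for GABA neuron markers and 0.0634 for the other lists). Without WT replicate 2 it called the respiratory chain only, while parvalbumin interneuron markers (-0.38), GABA neuron markers (-0.35) and vesicle release (-0.18) missed at an adjusted p of 0.0862. Without WT replicate 3 it called all but the parvalbumin interneuron markers, whose mean was -0.48 (adjusted p 0.146). With age as a covariate the parvalbumin interneuron markers (0.342) and vesicle release (0.0950) missed the threshold. The fits without an array normalised the remaining arrays anew, which also changed the means. In the main fit WT replicate 1 deviated by -0.079 for parvalbumin interneuron markers, so leaving out its values alone would not bring that mean nearer to WT. For the other lists it deviated by 0.16, 0.020 and 0.23 in the order above.

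**Figure D3:**
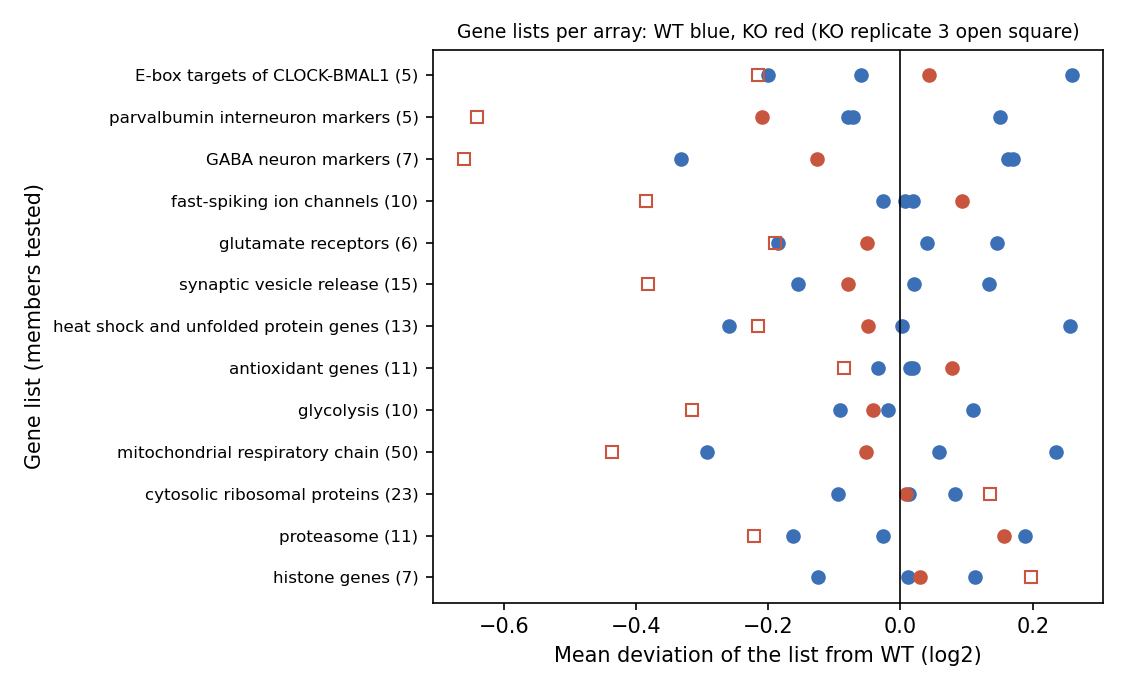
Mean log2 deviation of each of the 13 tested lists from WT on every array, with WT in blue, KO in red and KO replicate 3 as an open square; each WT array is set against the mean of the other WT arrays. KO replicate 3 is the lowest array for 10 of the 13 lists, the 4 that fell among them, with -0.44 for the respiratory chain, where KO replicate 1 is at -0.052.

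The other tested lists did not pass. Fast-spiking ion channels had a mean of -0.15 over 10 genes (camera adjusted p 0.348), with Kcnab2, a potassium channel subunit gene, below background on both KO arrays and at least 1.04-fold lower, with no bound left without WT replicate 1. This list passed only without KO replicate 1 (mean -0.45, camera adjusted p 0.0374). Glycolysis genes averaged -0.18 over 10 (0.324), led by the neuronal enolase gene Eno2 (-0.96, -0.37 without KO replicate 3), and glutamate receptor genes -0.12 over 6 (0.595), led by Gria3 (-0.67; -0.22 without WT replicate 1; its second probe was below background in KO). Heat shock and unfolded protein genes averaged -0.13 over 13 (0.348), led by the chaperone gene Hspa8 (-0.53, -0.079 without KO replicate 3, with its other 2 tested probes at -0.048 and 0.35), and this list passed only with age as a covariate (mean -0.30, camera adjusted p 0.0429). Ribosomal protein genes averaged 0.072 over 23 (0.840) and lay on both sides of 0, with Rpl38 at -0.66 and Rps14 at 1.00, but without KO replicate 3 these were -0.20 and 0.031. Proteasome genes averaged -0.033 over 11 (0.790; Psmd8 0.60, 0.14 without WT replicate 1), antioxidant genes -0.0036 over 11 (0.840; Park7 0.30, 0.099 without WT replicate 1) and histone genes 0.11 over 7 (0.717; H2ac13 0.71, -0.13 without KO replicate 3). For antioxidant genes the mean lay below 0, with the median and test above it, and for histone genes the median (-0.0042) lay below 0 and the mean and test above it.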

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

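Cyclic loess was chosen after seeing the data; the other alternatives were planned. No setting that kept both KO arrays called a probe at an adjusted p under 0.05. Of 801 values of named genes under the alternatives, 768 kept their direction and 33 did not, 18 of these under median scaling, and 4 passed the threshold, each without KO replicate 1 and 1 of them, Pvalb, on a value below background. All 4 called lists stayed lower under every alternative that gave them a value; the respiratory chain passed in 15 of 20, GABA neuron markers in 12 of 19, vesicle release in 10 of 20 and parvalbumin interneuron markers in 7 of 18. Signal near background limits the values of dim probes. Except where a construction is named, the cause was not tested.

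Leaving out 1 array at a time gave 0 (any array but KO replicate 1) to 27 called probes and 0 (WT replicate 1 or KO replicate 3) to 5 called lists (KO replicate 1). The list means then ranged from -0.68 to -0.22 for parvalbumin interneuron markers, -0.71 to -0.096 for GABA neuron markers, -0.41 to -0.083 for vesicle release, -0.49 to -0.056 for the respiratory chain, -0.45 to 0.10 for fast-spiking channels, -0.19 to 0.0016 for heat shock, -0.12 to 0.084 for antioxidant, -0.22 to 0.17 for proteasome, -0.34 to -0.030 for glycolysis, -0.21 to -0.055 for glutamate receptor, 0.027 to 0.15 for ribosomal, 0.031 to 0.24 for histone and -0.23 to 0.048 for E-box genes. Single genes ranged from -1.01 to 0.014 and -1.40 to 0.28 for the 2 Gad1 probes, -0.13 to 1.68 for H2ac13, -0.38 to 0.11 for Kcnc2, -0.53 to 0.20 for Rora, -0.057 to 0.17 for Tef, -0.43 to 0.15 for Tsc22d3, -0.011 to 0.26 for Tspan4 and -0.067 to 0.77 for Vamp1. The remaining arrays were normalised anew each time, so these ranges also carry the new normalization.

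Under median scaling the median of tested probes moved by -0.39, which by itself turns small positive differences. It does not account for larger ones that turned, such as those of Dbi (1.30 in the main fit) and Ndn (0.81). The means were -0.80 for E-box, -0.67 for antioxidant and -0.66 for ribosomal genes, each on the other side of camera's test. Genes that turned were Cblc (-0.16), Coq3 (-0.30), Cry2 (-0.35), Dbi (-0.44), H2ac13 (-0.40), Il18rap (-0.33), Kdm5b (-0.11), Magel2 (-0.39), Ndn (-0.53), Olfr48 (-0.15), Park7 (-0.73), Psmd8 (-0.27), Rps14 (-0.48), Tardbp (-0.36), Tef (-0.85), Tspan4 (-0.17), Ube4a (-0.11) and Vamp1 (-0.62). Without background correction camera's side turned for E-box (-0.014) and antioxidant genes (-0.0068), and after cyclic loess for E-box genes (-0.069) and Tef (-0.0099). On the authors' processed values parvalbumin interneuron markers (-0.42, adjusted p 0.0775) missed the threshold.

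With no filter, 1852 of 45281 probes had an unadjusted p under 0.05 and 1 list was called; parvalbumin interneuron markers (-0.15, adjusted p 0.187), GABA neuron markers (-0.19, 0.0539) and vesicle release (-0.12, 0.0539) missed, and E-box (-0.026), antioxidant (-0.013) and ribosomal genes (0.028) turned. At a detection p under 0.01, 1 of 10 lists was called; GABA neuron markers (-0.39, 0.0918) and vesicle release (-0.26, 0.381) missed and proteasome genes turned (0.053). With detection on all 5 arrays, 0 of 6 lists were called by camera; vesicle release (-0.21, 0.108) and the respiratory chain (-0.18, 0.0960) missed with fewer members, and ribosomal genes turned (-0.020). The unadjusted counts under these 2 filters were 58 of 1159 and 51 of 1038 probes.

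With an estimated correlation, fry's directional and fry's mixed test, 0 lists were called, at unchanged means of -0.42, -0.39, -0.23 and -0.24. Trend and robust eBayes left parvalbumin interneuron markers at -0.42 (adjusted p 0.0721). With age as a covariate these stood at -0.28, vesicle release at -0.19 and heat shock genes at -0.30, now called, while ribosomal (0.038) and histone genes (0.072), Kcnc2 (0.13) and Tsc22d3 (0.045) turned; Tsc22d3 also turned with array weights (0.077). An unadjusted p under 0.05 gave 198 probes, 92 of them with at least 1.5-fold. The log2 differences of the Clock probes between KO and WT were 0.13, -0.21 and 0.071 with age. They were 0.13 for the first without background correction and -1.95 for the second on the processed values, where values under 1 were set to 1. In the main fit they lay between -0.076 and 0.055. All Clock probes were below background, so none of these values measures a fold.

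Replicate numbers 1 and 3 are shared by the genotypes, but no label pairs the samples and 2 pairs are too few to show it; deviations from the group means correlated at 0.202 between the arrays numbered 1 and 0.129 between those numbered 3, but also at 0.102 between WT replicate 2 and KO replicate 3, and as 2 KO arrays deviate as mirror images these values are not independent. With a replicate block 0 probes and 2 lists were called, with parvalbumin interneuron markers at -0.37 and vesicle release at -0.19 (both adjusted p 0.0515), E-box at -0.11 and antioxidant genes at 0.0028 on the other side. The chip as a block was not run, as the tables name no chips.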

Other observations

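The tests of a single array, of the 4 lists against matched lists on single arrays, of other cell types and of fewer parvalbumin cells were chosen after the result they bear on was seen, and the bounds for a single array, for other cell types and for fewer parvalbumin cells were made stricter after their values were seen. The tests of brightness, of splits, of genomic copies and of proliferation markers were written down before their own values were seen. They too bear on patterns found in these data.

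KO replicate 3 had more outlying genes than the other arrays. On that array 40 of 2247 genes lay more than 1 log2 unit above the WT mean and 43 below, while the other arrays had at most 14 above and at most 4 below. The genes furthest above, named after their values were seen and not tested as a group, were Npm1 (10.06 on KO replicate 3, 6.87 on KO replicate 1 and 7.17 as the WT mean), the predicted genes Gm10052 (9.78, 6.95 and 7.40) and Gm6548 (10.35, 7.55 and 8.02), Rps14 (9.58, 7.63 and 7.60) and Snrpb (10.64, 8.23 and 8.68). Npm1 was above background on 1 of 3 WT arrays. Ribosomal protein genes as a list did not pass camera (adjusted p 0.840), and Rpl3 lay below WT on KO replicate 3 (7.74 against 8.93). Of the genes furthest below, Pvalb and Entpd4 were not above background on KO replicate 3, and Eno2 read 7.39 there against a WT mean of 8.96 and Nr1d2 7.40 against 8.88. Histone genes detected numbered 16 of 64 on KO replicate 3 and 10, 6, 5 and 6 on WT replicates 1, 2 and 3 and KO replicate 1. Of the 27 probes that limma called without KO replicate 1, 22 were higher, 14 of them with no gene name, and 5 lower, 3 of them below background on KO replicate 3.

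Ndn and Magel2, paternally expressed genes of the same imprinted region, read 8.75 and 8.12 and 7.98 and 7.84 on KO replicates 1 and 3, above the WT ranges of 7.37 to 7.88 and 7.35 to 7.45. For a single gene, chance alone separates the groups completely, in either direction, in 2 of 10 splits. Of Snurf, from the same region, the 2 probes detected on all 5 arrays differed by 0.14 and -0.62, and the Mkrn3 probe was below background on all arrays. For Nnt, a gene with an inherited deletion in the C57BL/6J strain that the labels name, 1 of 8 probes was tested. Ctcfl, a gene known mainly from testis and picked after its values were seen, read 13.01 ± 0.12 (SD, n = 3) in WT and 12.73 ± 0.20 (SD, n = 2) in KO. These values come from 1 probe and are among the brightest of the 2247 named genes tested. Whether the signal came from Ctcfl RNA was not tested.

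The fall of the 4 gene lists may rest on 1 array, KO replicate 3, without which 0 of the 4 passed, but this stays open. Without WT replicate 1, and with the remaining arrays normalised anew, camera also called 0. On KO replicate 1 the lists lay at percentiles 2.00 (parvalbumin interneuron markers), 6.70 (GABA neuron markers), 4.98 (vesicle release) and 0.910 (respiratory chain) of 10000 matched lists. On KO replicate 3 they lay at 4.97, 0.300, 2.47 and 0. Single WT arrays reached such extremes too: WT replicate 1 lay at 100 for the respiratory chain, and WT replicate 3 at 0.730 for GABA neuron markers and 0 for the respiratory chain. The percentiles on KO replicate 1 therefore decide nothing, as the lists were picked for low KO means and the genes of a list vary together. For brightness, 4 of the 4 means lay below the lowest 2.5% of 10000 random lists matched on mean level. The genes of the random lists were drawn independently, and the 4 lists had been picked as low against other genes. Falling below the 2.5% bound was therefore likely in advance and does not exclude brightness. The medians of these random lists were -0.080, -0.055, -0.041 and -0.016, against list means of -0.42, -0.39, -0.23 and -0.24. Typical genes of like mean level thus fell less than these lists. RNA of more cells of other types on KO replicate 3 cannot be told apart: 3 of 101 markers of excitatory neurons, glia, vessels and blood were detected there and 6 to 9 on the other arrays, but only 2 of the 8 tested markers were above background on all arrays. Of the 10 splits of the 5 arrays into 3 and 2, 2 gave as many lists. These were the real one with 4 and that of WT replicate 3 and KO replicate 3 also with 4. The remaining splits gave 0 to 3 lists, with 3 for that of WT replicates 1 and 2. In any case 10 splits are too few for a share under 0.05. The genotype stays open, and so does age, which differs by up to 4 days and could be fitted only as a covariate: GABA neuron markers (-0.42, camera adjusted p 0.0429) and the respiratory chain (-0.35, 1.0e-07) still passed, and parvalbumin interneuron markers (-0.28, 0.342) and vesicle release (-0.19, 0.0950) did not.

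Lower Pvalb in KO was weighed on KO replicate 1, the only KO array on which it was above background. On KO replicate 1 its deviation from the WT mean was -0.72, at percentile 1.5 of 200 genes of like mean level, but Pvalb was picked for low KO values, so KO replicate 3 as the whole cause cannot be excluded from 1 gene on 1 array. Fewer parvalbumin cells sorted for KO replicate 1 would lower the other markers too; the mean deviation of the other 4 there was -0.080 ± 0.071 (SE), against the -0.36 that is 0.5 of the Pvalb deviation, but 4 markers on 1 array exclude nothing, so this stays open. A lower Pvalb level per cell in KO, a single probe that hybridised differently and chance all remain open, and the tests above do not separate them.

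For the 40 genes raised on KO replicate 3, a candidate explanation is signal from sequences with many genomic copies, such as traces of DNA carried into the amplification. The 79 tested genes with a named pseudogene copy lay at percentile 60.3 of 10000 matched gene sets on that array. This is neither above the highest 2.5% nor below the median. The set overlaps the raised genes only in part. It holds Eef1a1 and Rps19, but not Npm1, Gm10052, Gm6548, Rps14 or Snrpb, the genes furthest above. The percentile therefore says little about the raised genes, and the explanation stays open. Dividing cells in the sort also stay open, with 2 of 24 proliferation markers detected on KO replicate 3 and 2 to 4 on the other arrays, and 3 tested. KO replicate 1 does not share the pattern as a whole, so no biological explanation from the design was tested. Dbi is an exception, at 1.39 above the WT mean on KO replicate 3 and 1.20 above it on KO replicate 1.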
